A study of Mus musculus with 8 samples.

How the data were processed

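RNA from the diaphragm of 8-week-old mice was measured on 8 Affymetrix expression arrays. 4 arrays carried normal muscle and 4 carried muscle of dy/dy mice, which have a laminin-deficient muscular dystrophy. Each array held muscle pooled from 3 mice, 12 mice per group, per the labels and the series' design text. The array, and so the pool, was the unit of replication. Pools of different mice are biological replicates, and pooling hides the spread between single mice.

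The authors deposited 1 table of signal intensity values on a linear scale, with 22690 probe sets, of which 64 are Affymetrix controls. Per the submitters' processing notes the values come from MAS5, the Affymetrix algorithm that subtracts a mismatch signal and scales each array. Its version, the hybridisation dates and the detection calls are not given in the sources used here. The deposited 2% trimmed mean was 500.2 on 7 arrays and 400.2 on normal replicate 4, so that array had been scaled to another target. MAS5 intensity values of dim probe sets are noisy, and a ratio of dim values is imprecise. The number of arrays, 4 per group, limits the precision of every comparison.

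Every array was rescaled to the mean of the 8 trimmed means, 487.7, by a rule that asked for rescaling when trimmed means differed by more than 10%. Signals quoted below are these rescaled values, as mean ± SD over 4 arrays. Tests used log2(signal + 16), and a log2 difference is dystrophic minus normal on that scale. The offset of 16 damps the noise of dim probe sets and makes a change of a dim gene smaller than the ratio of its signals. Controls and the probe sets in the lowest 40% by mean log2 value were left out, which left 13575 probe sets. Of the probe sets that are not controls, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none there. No gene was named from a probe set with several symbols. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 20364 matched. That table was used for names and for which genes lie near each other, and none of its coordinates are given, since the sources name no build. A gene was represented by its probe set with the highest mean log2 value, which gave 8214 genes.

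Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the 13575 probe sets and a threshold of 0.05. The 41 gene lists were fixed from general knowledge before the data were examined, and 40 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the 40 lists. Each was repeated with a correlation estimated from the data and with fry, which asks whether the members of a list move one way on balance. Calls among the members are given over all probe sets and, in addition, adjusted over the list alone. Probe sets of genes within 20 Mb of Lama2 were compared with those of other genes with a place in that table by a two-sided Fisher's exact test, with Lama2 itself left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

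The rule for the genes named in the text was also set before the data were examined. It takes Lama2, then the 10 largest rises and the 10 largest falls past the threshold among genes whose groups do not overlap and whose signal in the brighter group reaches the median of all probe sets, 192.2. Only 4 falls were eligible. It adds up to 4 called members of each list, or the 2 brightest members where none was called, every tested laminin chain, and Dmd, Utrn, Dag1, Itga7, Myh3, Myh8 and Myog. It gave 97 genes.

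Geometric mean signals of the poly-A spike-in controls, added to RNA before labelling, divided the arrays into 3 batches, each with equal numbers of both groups. Replicate 1 of each group lay at 549 to 595, replicate 3 of each at 312 to 360, and replicates 2 and 4 of each at 131 to 177. A fit with this batch as a block was added after the data had been examined, as were a fit to the values as deposited and a fit without normal replicate 4 and dystrophic replicate 3. The alternatives set in advance were offsets of 1 and 64, quantile normalization, a 75th percentile shift, no filter, a filter on the lowest 60%, no intensity trend, robust hyperparameters, array weights, the replicate number as a block, each array left out in turn, a threshold of 0.01, an estimated correlation, the mean of a gene's probe sets, and windows of 5 and 40 Mb.

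The fit was tested on simulated data for the comparison of dystrophic against normal, drawn with each probe set's mean in normal arrays and its spread within groups. In these 200 probe sets were changed, and 13575 probe sets passed the filter. It recovered 12 of 50 probe sets changed 1.5-fold, 36 of 50 changed 2-fold, 45 of 50 changed 4-fold and 39 of 50 changed 8-fold, with 6 false calls among 138. The bar first set for this test was recovery of over 80% of the 8-fold changes, and the result of 78% missed it. The 11 that were missed were falls that dropped below the filter and were never tested, while all 39 that were tested were recovered. After that result the bar was changed to recovery among the tested probe sets, and the fit itself was left as it was. Of the simulated 8-fold changes, 14 of 25 falls were recovered, against 25 of 25 rises. The changed probe sets were drawn from those past the filter and shifted from their mean in normal arrays. A fall could therefore drop below the filter and a rise could not. The filter uses the mean over all 8 arrays and can remove a strong change in either direction. This test does not show that it hides more falls than rises. With no filter, which adjusts over more probe sets, the data gave 52 higher and 1 lower. In simulated data with 1 list shifted by 0.4 on the log2 scale, camera called that list and 0 of 38 lists without its genes. The simulated probe sets were drawn independently of each other. In the data the estimated correlation reached 0.50 for the oxidative phosphorylation list and 0.87 for liver markers. The simulation therefore cannot show how often camera at the preset correlation calls a list wrongly in these data.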

Results

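Gene expression was measured in the diaphragm, the main muscle of breathing, of normal mice and of dy/dy mice, a strain with a severe muscular dystrophy caused by lack of laminin α2 in the basement membrane around muscle fibres. The comparison asks how transcript levels in dystrophic diaphragm differ from normal at 8 weeks of age. Each group had 4 arrays, and each array a pool of 3 mice. The median signal per array after rescaling lay between 172 and 207. Pearson correlations between arrays, across probe sets, ranged from 0.920 to 0.974. Normal replicate 4 and dystrophic replicate 3 lay at opposite ends of the first principal component, at -36.1 and 34.0, with the other 6 arrays between -11.47 and 12.52. The first component held 26.8% of the variance and the second 23.5%. On the second, replicate 1 of both groups stood apart, at 33.87 in normal and 25.95 in dystrophic, with the other 6 arrays between -16.82 and -2.48.

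Lama2, which encodes laminin α2, fell in dystrophic diaphragm. Its 1 probe set had a signal of 846 ± 101 (SD, n = 4) in normal and 270 ± 46.1 (SD, n = 4) in dystrophic pools, a log2 difference of -1.60 (SE 0.15, limma adjusted p = 8.91e-04). All 4 dystrophic pools, at 232 to 333, lay below all 4 normal pools, at 749 to 982. An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 allows. Within the 3 spike-in batches the difference was -1.21, -1.80 and -1.59. The sources used here do not place this probe set relative to the dy mutation, so it checks transcript level only.

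Of 13575 probe sets tested, 67 changed, 62 of them higher and 5 lower in dystrophic diaphragm. At least 2-fold changes numbered 45 up and 3 down. The representative probe sets gave 53 changed genes, 49 higher and 4 lower. The 10 largest rises that the naming rule allowed were those of Myh3, Myl4, Myh8, Ankrd1, Postn, Serpina3n, Mpeg1, Tubb6, Tnnt2 and Mybph. The 4 falls were Lama2, Grb14, Asb15 and Slc41a3. Of 12 changed genes with more than 1 tested probe set, 4 had every one called and 0 had one of opposite sign. Outside these, 3 genes had a called probe set and a tested one of opposite sign, and their representative probe set was not called. In all 67 probe sets the groups did not overlap, a property of 6.4% of tested probe sets against 2.86% by chance. At an unadjusted p under 0.05 there were 760 rises and 560 falls. The count fell to 34, 29 and 25 without dystrophic replicate 2, 3 or 4. With the spike-in batch as a block it was 114, and within the batch of 2 against 2 arrays it was 6, while the other batches held 1 array per group and allowed no test.

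Myh3, Myl4, Myh8 and Ankrd1, members of the list of myogenic regulators and regeneration markers, had the 4 largest increases among the named genes. Myh3, embryonic myosin heavy chain, had a signal of 9.26 ± 1.40 (SD, n = 4) in normal and 833 ± 229 (SD, n = 4) in dystrophic pools, with a log2 difference of 5.03 (SE 0.21, adjusted p = 7.02e-07). The normal value lies within the range of the TrpnX negative controls, 0.78 to 32.2, so the difference depends on the offset (3.58 with an offset of 64), and the dystrophic mean was 25.9 times the highest of those controls. Myl4, an embryonic and atrial myosin light chain, rose from 150 ± 26.8 to 1744 ± 489 (SD, n = 4), a log2 difference of 3.38 (SE 0.20, adjusted p = 1.44e-05), or 1.67 as the mean of this probe set and another, which was too dim to be tested. Myh8, perinatal myosin heavy chain, rose by 2.88 (SE 0.36) on the log2 scale. Ankrd1, a stretch-responsive protein of the sarcomere and nucleus, rose by 2.49 (SE 0.26). Tnnt2, cardiac troponin T, which fetal and regenerating skeletal muscle also express, rose by 1.93 (SE 0.28). Myog, the transcription factor myogenin, rose 2.83-fold (SE 0.26 on the log2 scale). Tubb6, a β-tubulin outside that list, rose by 1.97 (SE 0.36).

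**Figure D1:**
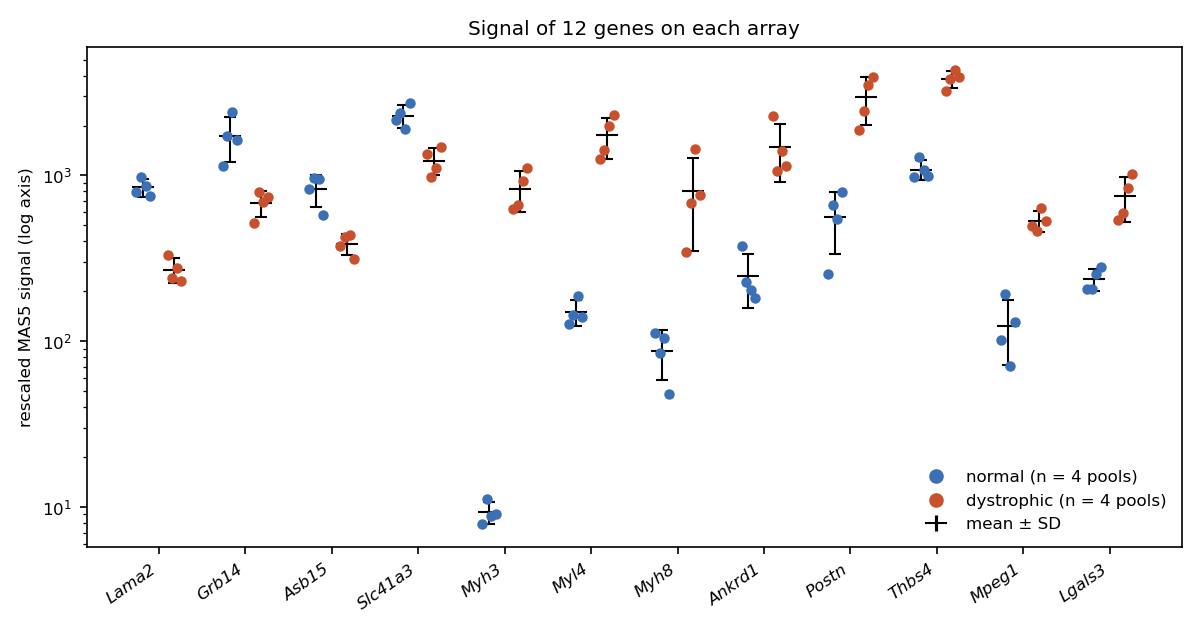
Rescaled MAS5 signal (log axis) of 12 genes on each of the 8 arrays, with normal pools in blue, dystrophic pools in orange, and bars for mean ± SD of 4 pools. The groups do not overlap for any of the 12 genes, which the rule for the largest rises and falls required of all but Thbs4 and Lgals3. Lama2 lies at 749 to 982 in normal and 232 to 333 in dystrophic pools, and Myh3 at 7.90 to 11.2 against 629 to 1114.

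In the list of myogenic regulators and regeneration markers, 9 of 26 tested members rose, 0 fell and 17 did not pass (14 rose adjusted over the list alone). Its median log2 difference was 0.56 (camera adjusted p = 1.56e-17, and adjusted p = 0.0308 with an estimated correlation). Myh3, Myl4, Myh8 and Ankrd1 passed in every leave-one-out fit that tested them. Myh3 was tested only in the fits without a normal array. With any dystrophic array left out it fell below the filter. Tnnt2 lost its call without dystrophic replicate 4 (adjusted p = 0.0552). Tubb6 kept its call only without normal replicate 4 or dystrophic replicate 1, and Myog only without dystrophic replicate 2, with adjusted p up to 0.171 and 0.115 otherwise.

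Genes of the interstitial matrix rose. In that list 8 of 38 members rose, 0 fell and 30 did not pass (20 rose adjusted over the list alone). Of the 38, 33 lay above 0, with a median log2 difference of 0.60 (camera adjusted p = 4.04e-20, and adjusted p = 0.0352 with an estimated correlation). Postn, periostin, a matrix protein of injured tissue, rose from 564 ± 229 to 2953 ± 947 (SD, n = 4), a log2 difference of 2.41 (SE 0.32, adjusted p = 0.00738). Thbs4, thrombospondin 4, rose by 1.81 (SE 0.14), and Lum, the collagen-binding proteoglycan lumican, by 1.24 (SE 0.14). Mfap2, a microfibril protein, rose by 1.18 (SE 0.21). Of 27 matrix proteases, inhibitors and collagen-processing genes, 2 rose, 0 fell and 25 did not pass (4 rose and 1 fell adjusted over the list alone). The 2 were Timp1, an inhibitor of metalloproteinases, which rose 2.83-fold (SE 0.18 on the log2 scale), and the gelatinase Mmp2, at a log2 difference of 0.81 (SE 0.15). A second tested Mmp2 probe set was at 0.55 and did not pass (adjusted p = 0.466), nor did the mean of both, at 0.68 (adjusted p = 0.112). This list had a median of 0.20 and a camera adjusted p of 0.00239, but adjusted p = 0.230 with an estimated correlation. Mfap2 kept its call only without normal replicate 2 or dystrophic replicate 1, and Mmp2 only without normal replicate 2, with adjusted p up to 0.115 and 0.174 otherwise.

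Fibroblast and fibro-adipogenic progenitor markers had 2 of 16 members that rose and 14 that did not pass (5 rose adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.00113. This list had adjusted p = 0.0528 with an estimated correlation. The risers were S100a4, at 1.47 (SE 0.23), and the microfibril gene Mfap5, at 0.95 (SE 0.15). S100a4 lost its call without normal replicate 2 or 3 or dystrophic replicate 2, 3 or 4 (adjusted p up to 0.0818), and Mfap5 kept its call only without normal or dystrophic replicate 1 (adjusted p up to 0.0936 otherwise). In the list of TGF-beta and fibrosis signalling, limma called 0 of 30 members, 10 had an unadjusted p under 0.05, all of them higher, and 4 rose adjusted over the list alone. Its median was 0.22 (camera adjusted p = 2.41e-04, and adjusted p = 0.0352 with an estimated correlation), and 0.13 without dystrophic replicate 1. Its 2 brightest members were Tgfbr2, a TGF-beta receptor, at 0.26 (SE 0.14), and Ltbp4, at -0.19 (SE 0.18), and neither passed.

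Macrophage and monocyte markers were higher. In that list 24 of 25 members lay above 0, 5 rose, 0 fell and 20 did not pass (17 rose adjusted over the list alone). The median was 0.66 (camera adjusted p = 4.04e-20, and adjusted p = 0.0349 with an estimated correlation). Mpeg1, a pore-forming protein of macrophages, rose from 124 ± 52.3 to 531 ± 75.1 (SD, n = 4), a log2 difference of 2.03 (SE 0.24, adjusted p = 0.00436). Lgals3, galectin 3, rose by 1.56 (SE 0.21), Gpnmb by 1.53 (SE 0.21) and Ctss, the lysosomal protease cathepsin S, by 1.33 (SE 0.16). Among 15 genes of the MHC and antigen presentation 3 rose, 0 fell and 12 did not pass (4 rose adjusted over the list alone). Their median was 0.24 (camera adjusted p = 1.89e-04, and adjusted p = 0.0352 with an estimated correlation). It was 0.16 without normal replicate 4 and 0.11 without dystrophic replicate 3. The 3 were class II genes, H2-Eb1 at 1.11 (SE 0.15), Cd74, the invariant chain, at 1.05 (SE 0.14) and H2-Aa at 1.00 (SE 0.13).

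Lysosomal genes had a median of 0.29 (camera adjusted p = 1.24e-05, and adjusted p = 0.0361 with an estimated correlation). Ctss was the 1 of 29 members that rose (8 adjusted over the list alone). Among 13 complement genes limma called 0, 6 had an unadjusted p under 0.05, all higher, and 4 rose adjusted over the list alone. The median was 0.45 (camera adjusted p = 3.48e-04, and adjusted p = 0.0476 with an estimated correlation). It was 0.27 with no filter and with the lowest 60% left out, and 0.11, 0.43 and 0.24 within the spike-in batches. The complement and macrophage lists as fixed share C1qa, C1qb and C1qc. Serping1, at 0.29 (SE 0.14), and Clu, at 0.14 (SE 0.39), were the brightest complement members, and neither passed. Clu had a signal of 4764 in dystrophic replicate 3, where liver transcripts were also high, and of 1044 to 2065 in the other dystrophic pools. The oxidative stress and NADPH oxidase list did not pass camera (median 0.07, adjusted p = 0.24) but passed fry (adjusted p = 0.00173). In it Cyba, a subunit of the phagocyte oxidase, rose by 1.08 (SE 0.15), a call lost without dystrophic replicate 4 (adjusted p = 0.05). Serpina3n, an acute-phase protease inhibitor, rose by 2.13 (SE 0.26).

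Of 17 genes of the neuromuscular junction or responsive to denervation, 3 rose and 14 did not pass (4 rose adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00352, and adjusted p = 0.230 with an estimated correlation). They were Myog, Chrna1, the acetylcholine receptor α subunit, at 1.18 (SE 0.14), and Ncam1, a neural adhesion molecule also made by regenerating fibres, at 1.41 (SE 0.24). All 3 also belong to the list of myogenic regulators and regeneration markers and are among its 9 risers. The neuromuscular list therefore adds no called gene to that list. Ncam1 kept its call only without dystrophic replicate 1 or 2 (adjusted p up to 0.121 otherwise). Cacng1, the γ subunit of the skeletal muscle calcium channel, rose by 1.22 (SE 0.17), the 1 of 31 calcium handling genes to do so. That list did not pass (median -0.10, camera adjusted p = 0.554). The Cacng1 call was lost without normal replicate 4 and dystrophic replicate 3 together (adjusted p = 0.0852).

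Ankrd2, a stretch-responsive gene of slow fibres, rose by 1.65 (SE 0.26), and lost its call without normal replicate 3 or dystrophic replicate 1, 3 or 4 (adjusted p up to 0.0672). It was the 1 of 14 slow-fibre genes to rise, and that list had a median of 0.25 (camera adjusted p = 0.0235, and adjusted p = 0.458 with an estimated correlation). The slow-fibre call was lost without normal replicate 2 (adjusted p = 0.368) or dystrophic replicate 1 (adjusted p = 0.0609). Ankrd1, Ankrd2 and Mybph, a myosin-binding protein at 1.85 (SE 0.23), were the 3 of 28 sarcomere, Z-disc and costamere genes that rose (4 adjusted over the list alone). That list did not pass, with a median of -0.03, a mean of 0.23 and a camera adjusted p of 0.244, but it passed with a median of 0.08 under quantile normalization (adjusted p = 0.0013) and of 0.03 without normal replicate 4, alone (adjusted p = 0.0341) or together with dystrophic replicate 3 (adjusted p = 0.0092).

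Genes of energy metabolism lay slightly lower as groups, with no member called. In the list of the TCA cycle and oxidative phosphorylation all 63 members lay below 0, with a median log2 difference of -0.18. limma called 0 of them and 5 had an unadjusted p under 0.05, all 5 lower. Camera gave an adjusted p of 3.63e-09, but adjusted p = 0.412 with an estimated correlation, and fry gave 0.281. The mean over the list was 13.3 ± 0.205 (SD, n = 4) on the log2 scale in normal and 13.1 ± 0.0786 (SD, n = 4) in dystrophic pools. Without normal replicate 4, the array with the highest list mean at 13.6, the median was -0.10, and under quantile normalization it was -0.06. Within the spike-in batches it was -0.01, -0.21 and -0.33. Atp5a1, a subunit of ATP synthase, had 24800 ± 6475 in normal and 21801 ± 1200 in dystrophic pools, and Cox6c, of cytochrome oxidase, 22562 ± 5687 and 18237 ± 2115 (SD, n = 4).

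The list of fatty acid uptake and oxidation had a median of -0.18 (camera adjusted p = 2.40e-04, and adjusted p = 0.362 with an estimated correlation), with 0 of 32 members called by limma and 5 at an unadjusted p under 0.05. Its brightest members were Fabp3, a fatty acid binding protein, at -0.19 (SE 0.13), and the lipase Lpl, at -0.32 (SE 0.18). Under quantile normalization the median was -0.09 (adjusted p = 0.00412). Glycolysis and glycogen genes had a median of -0.19 (camera adjusted p = 0.0234, and adjusted p = 0.362 with an estimated correlation), with 0 of 27 called, 4 at an unadjusted p under 0.05 and 1 that rose adjusted over the list alone. Aldoa was at -0.10 (SE 0.12) and Eno3 at -0.25 (SE 0.16). The glycolysis call was lost without dystrophic replicate 3 (adjusted p = 0.131) and under quantile normalization (adjusted p = 0.281), and its median was -0.09 without normal replicate 4. Fast-fibre contractile genes had a median of -0.23 (camera adjusted p = 0.0042, and adjusted p = 0.440 with an estimated correlation), with 0 of 16 called and 2 at an unadjusted p under 0.05. Atp2a1, the fast calcium pump, was at -0.23 (SE 0.17) and the troponin Tnni2 at -0.25 (SE 0.15). This median was -0.10 without normal replicate 4 and -0.03, not called, under quantile normalization (adjusted p = 0.607). Without normal replicate 4 and dystrophic replicate 3 together, the fast-fibre and glycolysis calls were lost, at -0.08 (adjusted p = 0.141) and -0.045 (adjusted p = 0.186), and the oxidative phosphorylation median was -0.06.

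**Figure D2:**
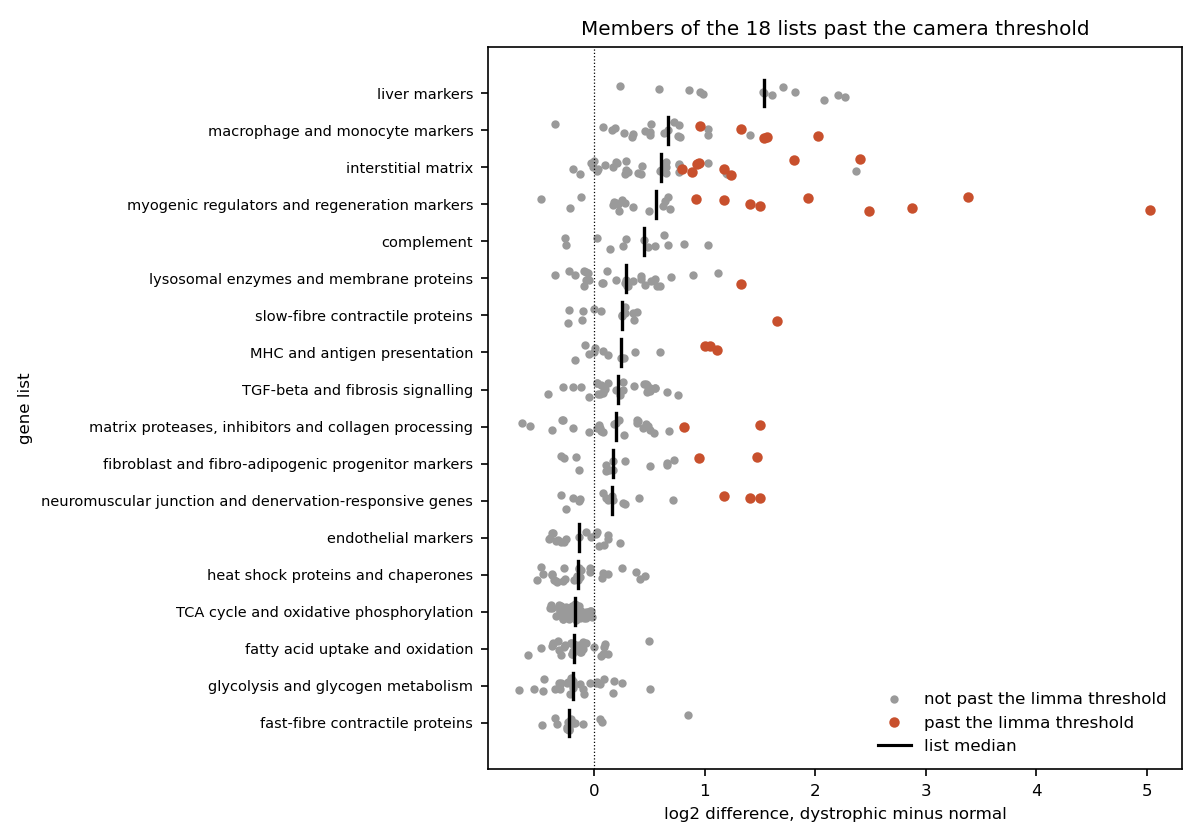
Log2 difference, dystrophic minus normal, of every tested member of the 18 gene lists past the camera threshold, with the list median as a bar and members past the limma threshold in orange. Members called by limma lie to the right of 0 in each list that has any, and all 63 members of the TCA cycle and oxidative phosphorylation list lie to the left of it.

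Grb14, an adaptor that restrains insulin receptor signalling, fell from 1730 ± 531 to 684 ± 122 (SD, n = 4), a log2 difference of -1.29 (SE 0.22, adjusted p = 0.025). Asb15, a muscle ubiquitin ligase adaptor, fell by 1.05 (SE 0.18), and Slc41a3, a magnesium transporter family member, fell by 0.90 (SE 0.16), with its 2 other tested probe sets at -0.87 and -0.59, which did not pass (adjusted p = 0.0657 and 0.282). Each kept its call in 1 of the 8 leave-one-out fits: Grb14 without normal replicate 1, Asb15 without normal replicate 4 and Slc41a3 without normal replicate 3, with adjusted p up to 0.0935, 0.132 and 0.137 otherwise. Igf2, a fetal growth factor, rose by 0.92 (SE 0.16, adjusted p = 0.029), the 1 of 26 genes of the IGF axis and growth factors to do so (2 rose and 1 fell adjusted over the list alone). Its call was lost without normal replicate 2, 3 or 4 or dystrophic replicate 3 or 4 (adjusted p up to 0.134) and on the mean of its probe sets (0.82, adjusted p = 0.226), and its list did not pass (median 0.13, camera adjusted p = 0.351).

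Apart from Lama2, the laminin chains and the proteins that link them to the fibre did not pass the test. Of 22 laminin and basement membrane genes 1 fell, Lama2, and 21 did not pass (1 fell adjusted over the list alone). The list median was 0.06 (camera adjusted p = 0.323). Lama4 was at 0.27 (SE 0.19), Lamc1 at 0.20 (SE 0.19), Lama3 at -0.15 (SE 0.17), Lama5 at -0.05 (SE 0.22), Lamc3 at 0.04 (SE 0.18), Lamb2 at -0.02 (SE 0.20) and Lamb1 at -0.01 (SE 0.20). Of 21 genes of the dystrophin-glycoprotein complex, integrins and glycosyltransferases limma called 0, with 2 at an unadjusted p under 0.05 and 2 that rose adjusted over the list alone, and the list did not pass (adjusted p = 0.351). Dmd, dystrophin, had a signal of 1173 ± 101 in normal and 1181 ± 137 in dystrophic pools (SD, n = 4). Its relative Utrn was at 0.13 (SE 0.17), the laminin receptor Dag1 at -0.13 (SE 0.15), Itga7 at -0.07 (SE 0.22) and Sspn at -0.11 (SE 0.16).

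Among probe sets of genes within 20 Mb of Lama2, limma called 0 of 124, against 63 of 12382 elsewhere (odds ratio 0, 95% interval 0 to 6.08, two-sided Fisher's exact p = 1). At an unadjusted p under 0.05 there were 16 of the 124, or 12.9%, against 1216 of the 12382, or 9.82%. Lama2 itself and probe sets with no placed gene, 1069 in all and 4 of them called, are in neither count.

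Liver transcripts were high in dystrophic replicate 3. All 13 members of the liver list lay above 0, with a median of 1.53 (camera adjusted p = 9.25e-06), but adjusted p = 0.406 with an estimated correlation. limma called 0 of them, and 5 had an unadjusted p under 0.05. Alb, serum albumin, had a signal of 18039 in dystrophic replicate 3, of 905 to 3245 in the other dystrophic pools and of 521 to 1347 in the normal pools. Cyp2e1 reached 8777 in dystrophic replicate 3 against 1351 to 2159 in normal pools. Without that array the list median was 0.58 (adjusted p = 0.00218). The same array had a BioC-5 hybridisation control of 8.78, against 401 to 1072 on the others.

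**Figure D3:**
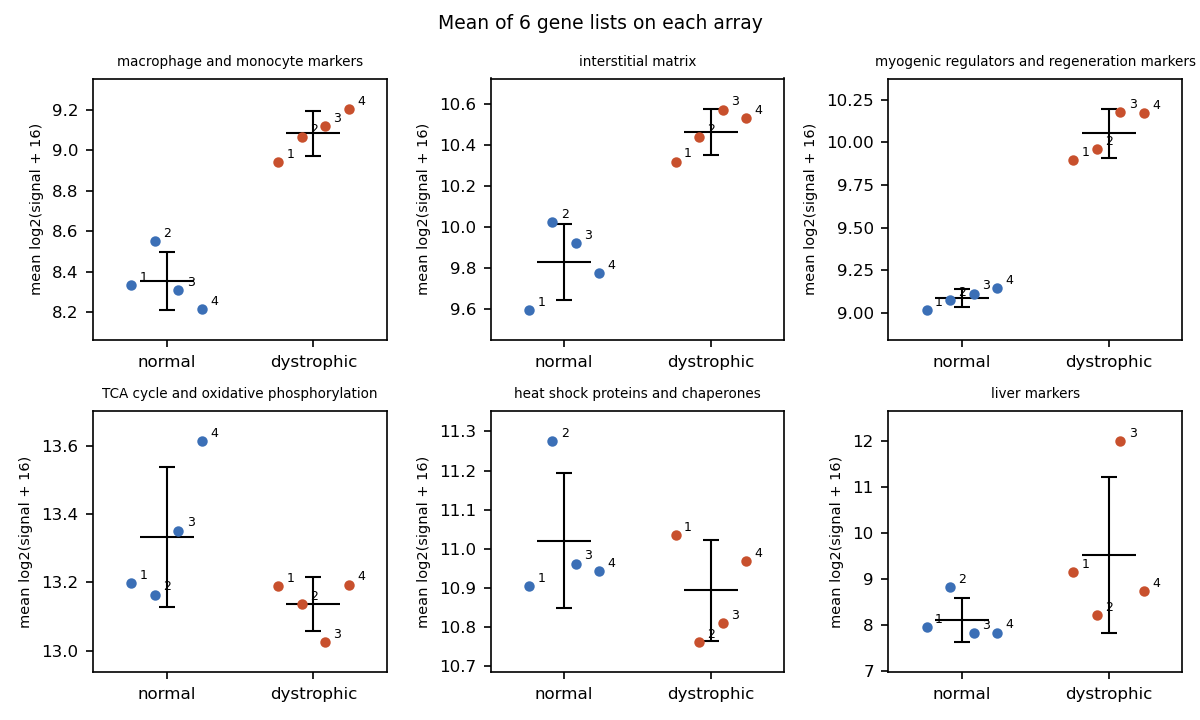
Mean log2(signal + 16) of the tested members of 6 gene lists on each array, with replicate numbers beside the points and bars for mean ± SD of 4 pools. The groups do not overlap for macrophage markers, interstitial matrix and regeneration markers, while dystrophic replicate 3 stands at 12.0 for liver markers and normal replicate 4 at 13.6 for oxidative phosphorylation.

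Heat shock proteins and chaperones had a median of -0.15 (camera adjusted p = 0.0234, and adjusted p = 0.406 with an estimated correlation), with 0 of 28 called and 3 at an unadjusted p under 0.05. Hspb1 was at -0.19 (SE 0.19) and Hspa8 at -0.38 (SE 0.17). The call was lost without normal replicate 2 (adjusted p = 0.222) or dystrophic replicate 2 (adjusted p = 0.203) or 3 (adjusted p = 0.0661). Endothelial markers had a median of -0.13 (camera adjusted p = 0.0407, and adjusted p = 0.412 with an estimated correlation), with 0 of 19 called and 5 at an unadjusted p under 0.05. Their brightest members Ramp2 and Esam lay at 0.04 (SE 0.14) and 0.09 (SE 0.16). That call was lost without normal replicate 1 or 2 or dystrophic replicate 3 or 4 (adjusted p 0.0519 to 0.173). The median was -0.09 without normal replicate 2 and -0.08 without dystrophic replicate 4, and -0.21, -0.21 and -0.22 without normal replicate 3, dystrophic replicate 1 or dystrophic replicate 2.

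In total 18 of 40 lists passed, 12 up and 6 down, and the same 18 passed with the spike-in batch as a block. With an estimated correlation 7 held: macrophage markers, interstitial matrix, regeneration, lysosome, MHC, TGF-beta and complement (adjusted p 0.0308 to 0.0476). fry called 11, and 10 of these were among the 18. Within the 3 spike-in batches the median was 0.71, 0.59 and 0.59 for macrophage markers, 0.58, 0.54 and 0.53 for interstitial matrix and 0.47, 0.58 and 0.66 for regeneration. Every called list kept its sign within each batch except heat shock, at 0.05 between the arrays of replicate 1. Between those arrays glycolysis was at -0.0024, oxidative phosphorylation at -0.0105 and fast-fibre genes at -0.0203, too small for their sign to say much. The batches of replicates 1 and 3 held 1 array per group, so their medians carry no measure of spread.

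Of the 22 lists that did not pass, 17 had no called member: limma called 0 of their 268 genes, and 40 had an unadjusted p under 0.05, 20 higher and 20 lower. Several of them mark other cells. Smooth muscle and pericyte markers had a median of -0.14 (camera adjusted p = 0.178), with Rgs5 at -0.25 (SE 0.29) and Acta2, smooth muscle actin, at 0.09 (SE 0.15). Schwann cell and nerve markers had a median of 0.12 (adjusted p = 0.233), with the myelin genes Pmp22 at 0.30 (SE 0.11) and Mbp at 0.40 (SE 0.19). That list passed with the lowest 60% left out, at 0.29 (adjusted p = 0.0354). Lymphocyte markers had a median of 0.33 (adjusted p = 0.323), with Ptprc, the pan-leukocyte antigen CD45, at 0.81 (SE 0.20) and Ighm, an immunoglobulin heavy chain, at 0.85 (SE 0.60). That list passed without normal replicate 2, at 0.49 (adjusted p = 0.0323). Neutrophil and mast cell markers had a median of 0.16 (adjusted p = 0.554), with the mast cell proteases Cpa3 at -0.28 (SE 0.17) and Cma1 at -0.02 (SE 0.15). Adipocyte markers had a median of -0.05 and a mean of 0.02 (adjusted p = 0.688), with Car3 at -0.50 (SE 0.20). The median was -0.08 for erythroid and blood markers (adjusted p = 0.538), with Fech at -0.16 (SE 0.12) and Pf4 at -0.08 (SE 0.16), and 0.16 for mesothelial markers (adjusted p = 0.82), with Upk3b at -0.07 (SE 0.17) and Igfbp5 at -0.23 (SE 0.17).

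Chemokines, cytokines and receptors had a median of 0.07 and a mean of -0.01 (camera adjusted p = 0.538), with the chemokine Cxcl12 at -0.58 (SE 0.14) and Tnfrsf1a at 0.25 (SE 0.12). Interferon-stimulated genes had a median of -0.07 (adjusted p = 0.383), with Ifitm3 at 0.03 (SE 0.13) and Irf1 at 0.05 (SE 0.15). Cell cycle genes had a median of 0.10 (adjusted p = 0.49), with Pcna at 0.23 (SE 0.15) and Cdkn2c at 0.13 (SE 0.18), and passed with no filter on dim probe sets, at 0.14 (adjusted p = 0.0238). Apoptosis and p53 targets had one of -0.03 (adjusted p = 0.606), with Ccng1 at -0.39 (SE 0.14) and Cycs, cytochrome c, at -0.18 (SE 0.20). The atrophy, proteasome and autophagy list had a median of 0.10 (adjusted p = 0.238), with Bnip3 at -0.10 (SE 0.11) and Sqstm1 at 0.16 (SE 0.11), and passed without normal replicate 4, at 0.12 (adjusted p = 0.0258), with array weights, at 0.16 (adjusted p = 0.0231), and without normal replicate 4 and dystrophic replicate 3 together, at 0.12 (adjusted p = 0.0283). Membrane ion channels and the sodium pump had a median of -0.11 (adjusted p = 0.267), with Fxyd1 at -0.15 (SE 0.14) and Atp1b1 at -0.12 (SE 0.15).

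Of the lists that check sampling, circadian output had a median of 0.07 (camera adjusted p = 0.554), with the clock-controlled factors Tef at 0.55 (SE 0.18) and Nr1d2 at 0.10 (SE 0.19). Immediate early genes had a median of 0.05 (adjusted p = 0.889), with Dusp1 at -0.15 (SE 0.27) and Nr4a1 at -0.48 (SE 0.28), and passed without dystrophic replicate 1, at 0.28 (adjusted p = 0.0459). Common reference genes had a median of 0.08 (adjusted p = 0.538), with Eef1a1 at 0.27 (SE 0.14) and Rps29 at -0.09 (SE 0.17). That list passed without normal replicate 4, at 0.10 (adjusted p = 0.0457), and under quantile normalization, at 0.14 (adjusted p = 0.0105), as did Eef1a1 under the latter, at 0.45 (adjusted p = 0.0158). Adjusted over the list alone, 2 circadian genes rose and 1 fell, 1 gene rose in each of the lymphocyte, ion channel and apoptosis lists, and 1 chemokine-list gene fell. The sex-linked list had 4 tested members, too few for a list test, and its Y-linked genes Eif2s3y and Uty were at 0.11 (SE 0.23) and -0.16 (SE 0.25).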

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

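The tests of dystrophy as the source of the liver transcripts and of dilution for the oxidative phosphorylation list were chosen after the result was seen. The margins by which a test had to decide were also made stricter after its values were seen, because several had decided by less than their own spread.

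Other divisions of the arrays did not give the 67 changed probe sets. Of the 35 splits of the 8 arrays into 4 and 4, only the real one, 1 split, gave as many, and the highest of the others gave 0. A share of 1 in 35 is the smallest this test allows. Every other split mixes the groups and puts their difference into the spread. The 0 therefore says little about how many calls would arise with no group difference.

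Liver transcripts such as Alb stood far above the other pools in dystrophic replicate 3 (gap over range 0.863 among the dystrophic pools). A second list of liver genes, not examined before, had 51 members with a probe set, of which 20 passed the filter and were tested. For 20 of these 20, or 100%, the highest signal was in dystrophic replicate 3, against 11.4% of other genes. Liver tissue carried over with that diaphragm would give this. The filter keeps a probe set by its mean over all 8 arrays, so a high value in that replicate helps a liver gene pass. The 100% is therefore partly fixed by the filter and covers the tested members only. Scaling of the array as a whole is argued against, since the list's median excess there exceeded that of brightness-matched random lists by 2.937 on the log2 scale, at 3.10 against 0.16, above all 10000 of them (highest 0.52). This excess rests on the same 20 tested members, which the filter helped to pick. Other faults of that array stay open, as its BioC-5 control was 8.78, against 401 to 1072 on the others. Dystrophy itself stays open as a source, as the list's median without that array was 0.58. In dystrophic replicate 2, 10 of 13 liver members, or 76.92%, lay within the range of the normal pools, but 4 and 6 did in replicates 1 and 4, and normal replicate 2 stood high in that range (list mean 8.83 against 7.83 to 7.96).

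The oxidative phosphorylation list lay lower in dystrophic pools, and no test settled why. Dilution of fibre RNA by other cells stays open: 79 fibre-restricted genes lay 0.1044 above the list (95% bootstrap interval 0.06 to 0.23), but members are correlated, and an exact permutation test over arrays gave p = 0.0571. Compression of bright probe sets could also contribute, since the list's median of -0.178 lay at percentile 1.45 of brightness-matched lists (median -0.11), with an interval of -0.224 to -0.16 that reaches past their lower 95% bound of -0.178. Quantile normalization, which gives every array the same distribution of signals, left a list median of -0.06 (camera adjusted p = 0.00277). The median of all tested probe sets was then -0.0253. The array of normal replicate 4 carries part of it, with a median of -0.09855 without that array (interval -0.122 to -0.0755), 55.4% of the whole. A shift shared by both groups of a spike-in batch cancels, as every batch held equal numbers of both, so it adds nothing to the -0.178, while a batch effect that differs between groups was not tested (medians within batches -0.01, -0.21 and -0.33).

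Heat shock genes lay lower as a list, and Cirbp, a cold-inducible RNA-binding protein, was at 1.01 (SE 0.21, limma adjusted p = 0.0657). Lower tissue temperature stays a possible explanation without a decision: a second list of 24 heat shock factor targets had a median of -0.06152 (camera p = 0.0719, and p = 0.348 with an estimated correlation). Compression of bright probe sets stays open as well, at percentile 0.98 of matched lists, since the median's interval of -0.281 to -0.0762 reaches past their lower bound of -0.131. Dilution by other cells stays open, since the list lay -0.07537 from fibre-restricted genes (interval -0.238 to 0.00152, exact permutation p over arrays 0.171).

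Of 281 groups of 4 arrays examined, 25 held an array whose gap to its nearest neighbour exceeded, as a share of the group's range, Dixon's 95% critical value, and chance gives about 5%. In normal replicate 4 these were Tnnt2 (0.87), Cox6c (0.856), Atp1b1 (0.881), Hspa8 (0.884) and the deposited trimmed mean (1). In normal replicate 1 these were Serping1 (0.845), Ncam1 (0.842), Cacng1 (0.921), Cdkn2c (0.901), the mean of erythroid and blood markers (0.963) and the 18S rRNA control (0.915, a signal of 763 against 63.4 to 123). In normal replicate 2 these were Ighm (0.924), Alb (0.929) and the list means of lymphocyte (0.869), heat shock (0.843) and liver markers (0.87). In dystrophic replicate 1 these were Cma1 (0.873), Atp2a1 (0.906), Utrn (0.898) and 18S rRNA (0.845, a signal of 471 against 123 to 177). In dystrophic replicate 2 these were Timp1 (0.869) and Ramp2 (0.946). In dystrophic replicate 3, besides Alb, these were the mean of interferon-stimulated genes (0.938) and the BioC-5 control (0.884, a signal of 8.78 against 492 to 556).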

How the results depend on the processing

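There were 23 alternatives set in advance and 3 chosen after seeing the data. In the 22 that refit it, Lama2 lay between -1.72 and -1.45 and passed at 0.05 (adjusted p up to 0.0127). The 67 called probe sets kept their direction wherever they were tested. Their groups do not overlap, so leaving out arrays, a block, or another offset or threshold could not turn it. Of 34 named called genes 17 kept their call in every alternative that tested them. Among these 34 genes 0 changed direction, which for the same reason most alternatives could not bring about. Of 2092 repeats of named genes 105 lost a call and 1 gained one, and of 916 repeats of lists 31 lost a call and 12 gained one, 3 of these with the median's sign turned. Leaving out 1 array at a time gave 25 to 61 changed probe sets, 23 to 57 higher, 1 to 5 lower, 22 to 48 changed at least 2-fold, and 15 to 21 lists, and 22 of the 67 calls were made in all 8 of these fits. The lowest count, 25, came without dystrophic replicate 4.

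A threshold of 0.01 gave 24 changed, 23 higher, 1 lower and 24 at least 2-fold, as a stricter threshold must give fewer. Leaving out the lowest 60% gave 29 at least 2-fold, with fewer probe sets tested. With no filter 1 was lower, and with no intensity trend 3 were. Array weights gave 127 changed, 114 higher and 13 lower. The replicate number as a block gave 105 changed and 12 lower. The main fit did not treat equal numbers as pairs, and their correlations were 0.484, -0.0455, 0.145 and 0.133. These correlations do not rule out shared processing, since the spike-in batches kept equal numbers together. Replicate 1 of both groups also stood apart on the second principal component, at 33.87 in normal and 25.95 in dystrophic. The main fit leaves variation shared in this way in the spread within groups, and a block takes it out. The spike-in batch as a block gave 114 changed, 101 higher and 13 lower, and leaving out normal 4 and dystrophic 3 together gave 31 changed, 29 higher, 2 lower and 29 at least 2-fold. An estimated correlation gave 7 lists. Apart from the threshold and the number tested, the cause was not tested. The sarcomere median, -0.03, turned to 0.07992 under quantile normalization, to 0.03198 without normal 4 and dystrophic 3 together, and ranged from -0.06135 to 0.04148 without 1 array; the cause was not tested. The odds ratio near Lama2 was 0 in all but the fit with the spike-in block, at 0.915 (exact p = 1), and was 0 at 5 and 40 Mb. With no filter, which adjusts over more probe sets, Tubb6, Grb14, Asb15, Slc41a3, Mfap2, Mmp2, Myog, Ncam1 and Igf2 lost their calls. Tubb6 also lost its call under quantile normalization (0.0536), robust hyperparameters (0.0596) and no intensity trend (0.0544), Slc41a3 (0.0587), Mmp2 (0.0743) and Igf2 (0.0503) under the last, and Asb15 in the values as deposited (0.12). Without normal 4 and dystrophic 3 together, calls were lost for Mybph (0.0534), Gpnmb (0.0852), Cacng1, Grb14, Slc41a3, Mfap2, Mmp2, Myog, Ncam1, Igf2, S100a4 and Mfap5 (up to 0.233) and for heat shock (0.0834) and endothelial markers (0.146), the neuromuscular median was 0.09 and the fatty acid median -0.12. The neuromuscular (adjusted p = 0.0686) and endothelial lists (0.0648) lost theirs with the lowest 60% left out, and glycolysis (0.0543) and endothelial markers (0.112) on the mean of probe sets. The complement median was 0.27 with no filter and with the lowest 60% left out, and the fibroblast median 0.39 with the latter and 0.27 on the mean of probe sets. In the values as deposited, medians were -0.10 for oxidative phosphorylation and fatty acids, -0.11 for glycolysis, -0.15 for fast fibres, -0.07 for heat shock and -0.06 for endothelial markers. Signal over background limits dim genes: Myh3, near background in normal pools, was below the filter and not tested with an offset of 1, with the lowest 60% left out, or without any 1 of the dystrophic arrays.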

Other observations

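Of the 53 changed genes, 19 lie outside the rule for named genes and were chosen for mention after their values were seen. All 19 rose. Among them are the collagen genes Col1a2, at a log2 difference of 0.88 (SE 0.14, limma adjusted p = 0.0167), and Col6a3, at 0.79 (SE 0.12). Mgp, matrix Gla protein, an inhibitor of calcification, rose by 0.93 (SE 0.14), from a signal of 3465 ± 464 to 6626 ± 931 (SD, n = 4). The macrophage marker Cd68 rose by 0.96 (SE 0.15), Lsp1, a leukocyte protein, by 0.94 (SE 0.16), and Nox4, an NADPH oxidase, by 1.01 (SE 0.18). Dsp, desmoplakin of desmosomes, rose by 1.78 (SE 0.20), Psca by 1.75 (SE 0.27) and Dclk1, a microtubule-associated kinase, by 1.23 (SE 0.18). Tmsb10, an actin-binding thymosin, rose by 0.93 (SE 0.15) and Tspo, a protein of the outer mitochondrial membrane, by 0.69 (SE 0.13).

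Imprinted genes beside Igf2 were also examined after values were seen. Peg3 rose by 1.06 (SE 0.16, limma adjusted p = 0.0133). Plagl1 was at 0.90 (SE 0.20), Meg3 at 0.69 (SE 0.17), Mest at 0.67 (SE 0.16) and Impact at -0.65 (SE 0.16), and none of these 4 passed. A hypothesis that imprinted genes rise as a set was not decided. The 13 tested imprinted genes whose values had not been seen had a median of 0.1939, with 10 above 0. limma called 0 of them and 1 had an unadjusted p under 0.05. As a set they had a camera p of 0.146.

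Xist, the transcript of the inactive X chromosome, had a signal of 453 in dystrophic replicate 4 and of 113 to 242 on the other arrays. Each array is a pool of mice, whose sexes are not given in the sources used here.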
